A study of Mus musculus with 8 samples.

How the data were processed

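Mouse colon epithelium grown as colonoids was profiled by droplet single cell RNA sequencing (10x v3 chemistry, counting the 3' ends of transcripts). The 8 libraries form 4 groups of 2: Nox1 wildtype untreated, Nox1 wildtype with TNF, Nox1 knockout untreated and Nox1 knockout with TNF. Per the labels, TNF was given for 48 hours, at a dose that the labels do not give. All 8 libraries, the untreated ones included, had medium with 25% WRN conditioned medium, 20 µM DAPT (which blocks Notch signalling) and 5 µM Y27632. Groups were taken from the labels. The short description codes pair each untreated library with a TNF library of the same named line (WT2, WT3, KO2 and KO4). Only these codes name a line. The titles number the libraries of a group as biological replicates, and within a genotype these numbers give the same pairs. The blocked alternatives rest on these labels alone. Nothing in the labels says that the lines came from separate animals, so p-values measure only the spread between these libraries.

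The deposited matrices hold counts, as whole numbers of UMIs per gene and barcode, which the authors made with Cell Ranger 3.1.0 on mm10 per the submitters' processing notes. The deposited barcode and feature lists hold other, non-numeric contents: the barcodes and the gene IDs with symbols. Each library lists 6794880 barcodes, the whole unfiltered list, and 31053 genes, of which 30934 gene IDs were found in GENCODE M21, used for locations. The gene annotation of the counting step is not stated. No column was taken from another series.

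A barcode was kept as a cell when it held at least the larger of 1000 UMIs and the 99th percentile of the top 3000 barcodes of its library divided by 10, at least 500 genes and at most 20% mitochondrial UMIs. The barcodes with the highest Scrublet doublet scores (scanpy 1.11.5, 30 components, seed 1) were then removed at 0.8% per 1000 cells. This kept 34012 cells. In the order replicate 1 untreated, replicate 1 TNF, replicate 2 untreated, replicate 2 TNF, the libraries labelled wildtype kept 3075, 2950, 5054 and 4281 cells with medians of 13254, 14898, 12558 and 15738 UMIs, and the libraries labelled knockout kept 3275, 5418, 5036 and 4923 cells with medians of 7165, 15639.5, 12557.5 and 14517 UMIs. Free RNA, taken from barcodes ranked 12001 to 60000 by UMIs, was estimated at 12.14% of the UMIs in cells of knockout untreated replicate 1 and at 0.34% to 1.42% in the other 7 libraries.

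Raw UMI counts were summed per library over the cells kept and tested with edgeR 4.0.16 (quasi-likelihood fit, robust, TMM scaling, genes kept by filterByExpr by group), with 4 group means and 4 residual degrees of freedom. This left 14754 genes tested in 7 contrasts: TNF in each genotype, genotype in each treatment, the TNF by genotype interaction, TNF averaged over genotypes and genotype averaged over treatments. P-values were adjusted over genes by the Benjamini-Hochberg method within a contrast, a gene was called at an adjusted p under 0.05, and all tests were two-sided. Errors beside log2 fold changes are the absolute log2 fold change divided by the square root of the quasi-likelihood F statistic. They approximate a standard error and are not reliable where counts or changes are near 0. Errors beside means are standard deviations over 2 libraries. Correlation between replicates over 6609 genes was 0.9903, 0.9932, 0.9841 and 0.9942 in the 4 groups in the order named first.

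Before the data were examined, 32 gene lists were fixed, of which 31 had enough tested genes (all but red blood cell markers): antimicrobial and IL-17-type response, antioxidant, cholesterol synthesis, colonocyte, deep crypt secretory, endoplasmic reticulum stress, enteroendocrine, fibroblast and endothelial, goblet, hypoxia and glycolysis, immediate early and dissociation, immune, interferon response, M cell markers, MHC class I, MHC class II, mitochondrially encoded, NADPH oxidase, NF-kB targets, Notch pathway, nuclear oxidative phosphorylation, Paneth, proliferation, RANK, regenerative and fetal-type, ribosomal protein, sex-linked, stem and Wnt, tight junction, TNF receptor and cell death, and tuft. They were tested with camera (limma 3.58.1, voom weights, preset correlation 0.01, adjusted over the lists of a contrast), again with an estimated correlation, and with fry. The estimated form rests on the 4 residual degrees of freedom, so few lists can pass it, and a call lost there leaves a list undecided. Pla2g2a, Ccn1, Ccn2 and Trop2 matched no symbol in the files.

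Cells were clustered in Seurat 5.3.0 (RPCA integration over the 8 libraries, 2000 variable genes, 30 components, Louvain resolution 0.8, seed 1). A cluster was named after 1 of 13 marker classes when at least 3 markers of that class were up at a log2 fold of at least 1 and detected in at least 10% of its cells, and when no other class had more markers among its top 10 genes by fold; clusters of low depth without a marker there were not named. These naming thresholds, the merging of deep crypt secretory into goblet-like cells and the window of barcodes for free RNA were set after the data were seen; the other clusters stayed unnamed. Class sizes move with small numerical differences between runs of the clustering: 3 runs gave clusterings that were not identical, and embeddings were rounded before clustering to make the partition repeatable. Shares of a class per library were compared by exact permutation of treatment within genotype or of genotype within treatment. Each has 36 relabelings, so that the smallest p is 0.0556, adjusted over the classes. With 2 libraries against 2 there are 6 relabelings and the smallest p is 0.3333, so no p is given for these. Intervals of 95% for a share are binomial and cover counting error alone. Within a class that had at least 20 cells in every library, the edgeR test was repeated on UMIs summed over its cells.

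The named genes were chosen by a rule: in each contrast, among called genes with an average log2 CPM of at least 4 and with all libraries of one arm above the other, the 10 with the largest fold in each direction without predicted, mitochondrially encoded or ribosomal protein genes. In every contrast Nox1, Noxo1, Noxa1, Cyba, Duox2, Nos2, Lcn2, Cxcl1, Ccl20, Tnfaip2, Tnfrsf11b, Spib, Gp2, Muc2, Lgr5 and Car1 were added, with up to 4 members with the smallest p of each list described. Where none passed, the 5 with the smallest p in each direction were taken. Within a class the rule took the 5 with the smallest p in each direction. The contrasts, tests, cell rule, lists, marker classes, named-gene rule and main alternatives were fixed before the data were examined.

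The alternatives were leaving out each library, DESeq2 1.42.0 as the test, DESeq2 size factors, no gene filter, a filter of 10 CPM in 2 libraries, cell thresholds of 1000 or 5000 UMIs, mitochondrial limits of 10% or 40%, no doublet removal, free RNA subtracted, mitochondrial and ribosomal genes left out, a block for the line or replicate number, Louvain resolutions of 0.4 and 1.2, and no integration. The pairing was checked on 6609 genes: deviations of the paired libraries from their group means correlated at 0.350 in wildtype and 0.188 in knockout, against 0.320 for untreated and 0.005 for TNF libraries that share only a replicate number across genotypes. The blocked fits add terms for the lines or the replicate number, so they leave fewer residual degrees of freedom than the main fit. This alone is no reason to discount a p-value, and for TNF and the interaction the block compares libraries within a line. The reason for their much smaller p-values at nearly the same effect sizes was not tested. These p-values are therefore printed beside the main ones and not read as stronger evidence. The edgeR test was also tested on simulated data, in which 200 genes were changed. With 2-fold changes it recovered 67.2% for TNF in 1 genotype, 86.4% for TNF averaged, 73.8% for genotype averaged and 50.7% for the interaction, and of 4-fold interactions 74.2%. Unchanged genes made up 13.7%, 7.6%, 9.1% and 12.1% of the calls in those 4 tests. Other software was R 4.3.3, data.table (version 1.17.8), Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9.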

Results

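The 8 libraries of mouse colonoid epithelium held 34012 cells, 2 libraries for each of 4 groups: Nox1 wildtype or knockout, untreated or given TNF for 48 hours. The series title names TNF-induced reactive oxygen species and M cell differentiation. The questions were which genes and cell classes TNF changed, which differed by genotype, and whether the TNF change differed by genotype. Median UMIs per cell lay between 12557.5 and 15738 in 7 libraries and at 7165 in knockout untreated replicate 1. In that library 27.9% of all UMIs fell in the cells kept, 23.78% of barcodes at cell depth were lost to the mitochondrial limit and free RNA was estimated at 12.14% of cell UMIs. The other 7 libraries had 71.85% to 86.9% of UMIs in cells and 0.34% to 1.42% free RNA.

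The gene that names the genotypes went against its label. Nox1 (ENSMUSG00000031257, chromosome X, 134086421 to 134221956) encodes the superoxide-making NADPH oxidase of colon epithelium. It was present in the libraries labelled knockout at 47.0 ± 6.18 CPM untreated and 77.9 ± 7.26 CPM with TNF, against 5.07 ± 1.59 and 22.7 ± 2.43 CPM in the libraries labelled wildtype (TMM-scaled mean ± SD, n = 2 each). The difference was 2.49 ± 0.14 log2 units over both treatments (edgeR adjusted p 1.68e-06). All 4 libraries labelled knockout lay above all 4 labelled wildtype, and the call held with each library left out in turn. It was 3.20 ± 0.20 untreated (adjusted p 2.11e-05) and 1.78 ± 0.18 with TNF (0.000239). Nox1 also differed inside classes of cells: 4.0 ± 0.30 in colonocyte-like, 3.69 ± 0.22 in regenerative-like and 2.23 ± 0.12 in proliferating-like cells. The sizes in the colonocyte-like and regenerative-like cells rest on few UMIs in the libraries labelled wildtype (untreated, 0 and 4 in colonocyte-like and 5 and 2 in regenerative-like cells). TNF raised Nox1 by 2.14 ± 0.20 in the libraries labelled wildtype (edgeR adjusted p 0.00043, 2 against 2 libraries). In the libraries labelled knockout the change was 0.73 ± 0.18 (0.0474). That call was lost without knockout untreated replicate 1 (0.315), knockout TNF replicate 1 (0.114) or 2 (0.262), or wildtype TNF replicate 1 (0.0656) or 2 (0.0649). The interaction was -1.42 ± 0.26 (edgeR adjusted p 0.466; 0.0303 without wildtype untreated replicate 2; with the line as a block -1.44, adjusted p 1.17e-14). The labels do not say which part of Nox1 was deleted, and 3' tags from outside that part check nothing about the genotype. Every direction between genotypes below is a direction between labels.

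**Figure D1:**
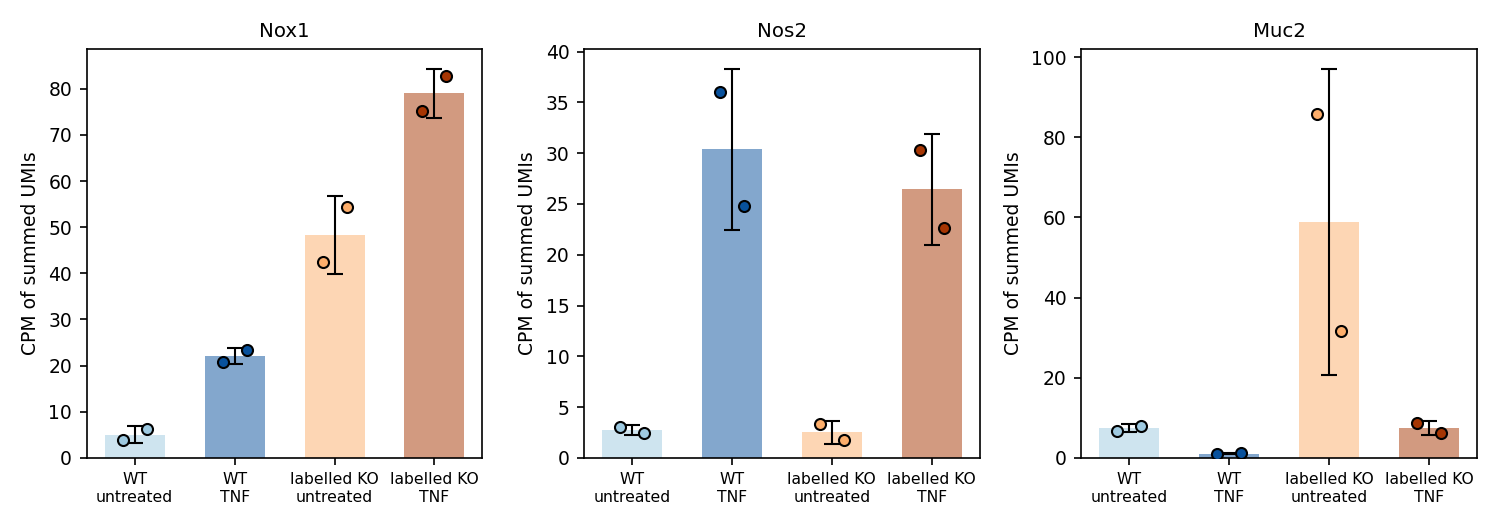
CPM of summed UMIs for Nox1, Nos2 and Muc2, 1 point per library, bars the mean and error bars the SD of each group (n = 2). Nox1 lies at 42.4 to 82.8 CPM in the libraries labelled knockout against 3.75 to 23.3 in those labelled wildtype, Nos2 is higher in each TNF library than in every untreated library, and Muc2 falls from 85.9 and 31.8 CPM to 8.66 and 6.26 with TNF in the libraries labelled knockout.

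What TNF changed over both genotypes was asked with 4 TNF against 4 untreated libraries. Negative-feedback and inflammatory targets of NF-kB rose. Tnfaip3 (ENSMUSG00000019850, chromosome 10), which ends NF-kB signalling, rose by 1.79 ± 0.10 log2 units (edgeR adjusted p 2.63e-07) and Nfkbia (ENSMUSG00000021025, chromosome 12), the inhibitor that holds NF-kB in the cytoplasm, by 1.70 ± 0.11 (1.48e-06). Tnf itself (ENSMUSG00000024401, chromosome 17) rose by 1.87 ± 0.11 (8.1e-07) and the adhesion molecule Icam1 (ENSMUSG00000037405, chromosome 9) by 1.87 ± 0.17 (0.000359). Enzymes and subunits for reactive oxygen and nitrogen species rose as well. Inducible nitric oxide synthase Nos2 (ENSMUSG00000020826, chromosome 11) rose by 3.5 ± 0.26 (0.000676), dual oxidase Duox2 (ENSMUSG00000068452, chromosome 2) by 1.64 ± 0.16 (0.000122) and Nox1 by 1.44 ± 0.13 (0.000125). So did the Nox1 partner subunits Cyba (ENSMUSG00000006519, chromosome 8) by 0.82 ± 0.11 (0.000301), Noxo1 (ENSMUSG00000019320, chromosome 17) by 0.54 ± 0.08 (0.000824) and Noxa1 (ENSMUSG00000036805, chromosome 2) by 0.42 ± 0.09 (0.00711). The neutrophil attractant Cxcl1 rose by 1.66 ± 0.15 (1.74e-05), complement component C3 (ENSMUSG00000024164, chromosome 17) by 4.0 ± 0.17 (1.22e-08) and the oxidase regulator Ncf4 (ENSMUSG00000071715, chromosome 15) by 3.56 ± 0.11 (5.98e-10). Genes of mucus-secreting cells fell. Tff3 (ENSMUSG00000024029, chromosome 17), a mucosal repair peptide, fell by 2.61 ± 0.31 (0.00646) and Sval1 (ENSMUSG00000029865, chromosome 6), a secreted protein, fell by 3.14 ± 0.20 (0.000111). Atoh1 (ENSMUSG00000073043, chromosome 6), the regulator that sets the secretory fate, fell by 1.18 ± 0.14 (0.000915). These genes were called with each library left out, and the Noxa1 call was lost with cells at 1000 UMIs. Muc2 (ENSMUSG00000025515, chromosome 7), the main mucin, fell by 2.88 ± 0.43 (0.0224). That call was lost without wildtype untreated replicate 1 (0.0805) or 2 (0.0917), wildtype TNF replicate 1 (0.104) or 2 (0.0867), or knockout TNF replicate 1 (0.0949) or 2 (0.115). The chemokine Ccl20, which draws immune cells to the epithelium, rose by 3.81 ± 0.40 (0.00672; 0.0502 without wildtype untreated replicate 2 and 0.0511 with the line as a block). In all, 1628 of 14754 genes were called, 814 in each direction. This became 877 without wildtype TNF replicate 1, 1080 without wildtype untreated replicate 2, 1021 without knockout TNF replicate 2 and 2693 without knockout untreated replicate 2. With the line as a block it was 3577.

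Of the 31 lists, camera called 16 for TNF over both genotypes. Each of the 16 calls was lost when the correlation between genes was estimated, a form with 4 residual degrees of freedom that few lists can pass. Up were NF-kB targets (22 of 29 members called up, 27 when adjusted over the list alone; median log2 fold change 1.31, adjusted p 7.87e-31; adjusted p = 0.153 with an estimated correlation). So were the NADPH oxidase subunits (7 up and 1 down of 11, the same counts adjusted over the list alone; 4.37e-07; adjusted p = 0.153 with an estimated correlation). Proliferation genes were up (11 up of 22, 16 adjusted over the list alone; median 0.29, 5.8e-10; adjusted p = 0.301 with an estimated correlation). Among them Aurkb, a kinase of chromosome segregation, rose by 0.52 ± 0.08. MHC class I, which presents antigen, was up (7 of 14 members, 8 adjusted over the list alone; 1.16e-06). So were the interferon response (9 of 23, 12 adjusted over the list alone; 2.64e-06) and regenerative and fetal-type genes (4 of 16, 7 adjusted over the list alone; 1.26e-05), all 3 with adjusted p = 0.301 with an estimated correlation. Down were goblet genes (15 of 20, 18 adjusted over the list alone; median -2.08, 1.37e-19) and deep crypt secretory genes (5 of 9, also 5 adjusted over the list alone; 0.00013), each at adjusted p = 0.301 with an estimated correlation. The enteroendocrine list was called down by camera too (5 of 22, 17 adjusted over the list alone; 4.78e-08; adjusted p = 0.361 with an estimated correlation). M cell markers (7 up and 1 down of 17, 8 and 2 adjusted over the list alone; 0.000284) and TNF receptor and cell death genes (9 and 1 of 23, 12 and 2 adjusted over the list alone; 0.000284) were up at adjusted p = 0.301 with an estimated correlation. At that same value antimicrobial genes (11 and 2 of 22, 12 and 4 adjusted over the list alone; 0.000381) and antioxidant genes (6 and 2 of 22, 10 and 3 adjusted over the list alone; 0.000889) were up. RANK pathway genes (3 and 1 of 10, 4 and 1 adjusted over the list alone; 0.000879) were up at adjusted p = 0.212 with an estimated correlation.

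The last calls for TNF over both genotypes were weaker, both at adjusted p = 0.5 with an estimated correlation. Cholesterol synthesis was down (2 of 18, 6 adjusted over the list alone; 0.00652; 0.0864 without knockout TNF replicate 2 and 0.0502 with the line as a block). Immediate early genes were up (3 and 1 down of 20, the same adjusted over the list alone; 0.0493; 0.0612 without wildtype untreated replicate 1, 0.0805 without knockout untreated replicate 1 and 0.215 without knockout TNF replicate 1). The 15 lists not called by camera were Paneth (adjusted p 0.0839), MHC class II (0.117), mitochondrially encoded (0.204), nuclear oxidative phosphorylation (0.259), colonocyte (0.279), Notch pathway (0.279), endoplasmic reticulum stress (0.352), hypoxia (0.413), stem and Wnt (0.486), sex-linked (0.489), tuft (0.501), tight junction (0.683), fibroblast and endothelial (0.76), ribosomal protein (0.76) and immune (0.776). The median and mean differed in sign for MHC class II (-0.15 and 0.82, test up), the Notch pathway (-0.11 and 0.08, test down), fibroblast and endothelial (0.28 and -0.32, test up) and tight junction genes (0.03 and -0.12, test down). For stem and Wnt genes both were negative (-0.07 and -0.06) and the test was up. Red blood cell markers had too few tested genes.

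**Figure D2:**
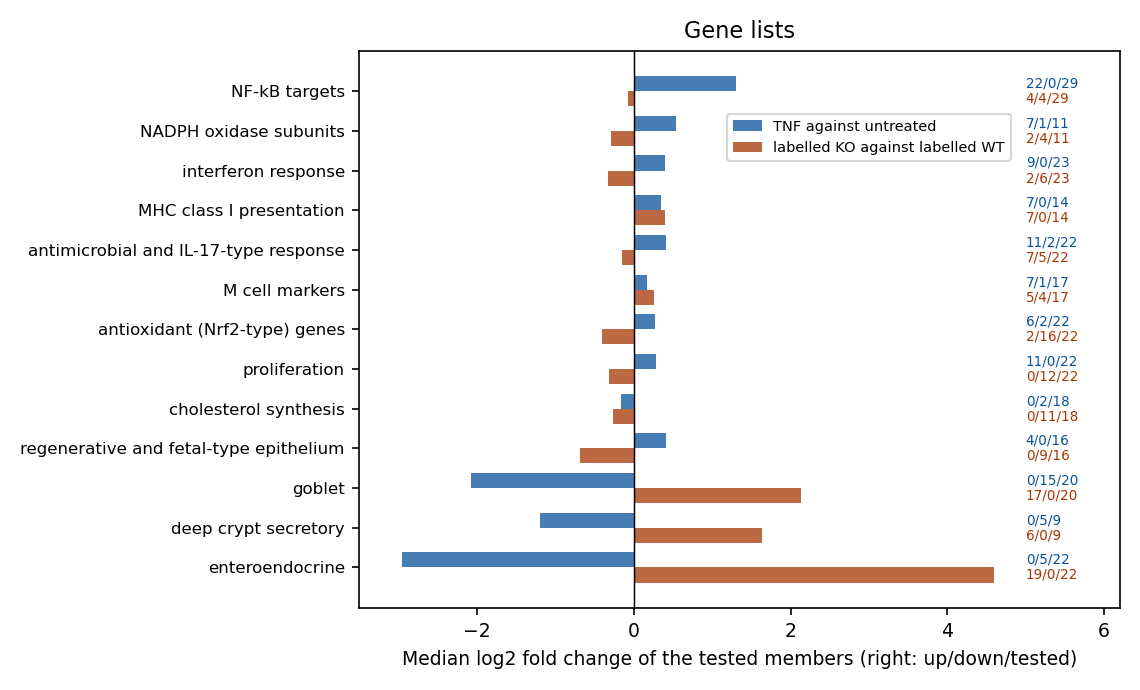
Median log2 fold change (bars, x axis) of the tested members of 13 fixed gene lists, blue for TNF against untreated and brown for libraries labelled knockout against wildtype, with the members called up, called down and tested at the right. NF-kB targets stand at 1.31 for TNF averaged over genotypes and goblet genes at -2.08, while for genotype goblet genes stand at 2.14; fitted values of enteroendocrine genes near 0 UMIs in wildtype TNF libraries set no bound on their fold.

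TNF in each genotype was asked with 2 against 2 libraries. In the libraries labelled wildtype the feedback gene Tnfaip3 rose by 1.80 ± 0.14 (edgeR adjusted p 1.98e-05), Duox2 by 2.06 ± 0.22 (0.000771) and C3 by 2.83 ± 0.22 (2.1e-05). The cystine transporter Slc7a11 (ENSMUSG00000027737, chromosome 3) rose by 0.90 ± 0.14 (0.00308), and Atoh1 fell by 1.60 ± 0.20 (0.00302) and Sval1 fell by 4.06 ± 0.30 (0.000693). In those labelled knockout Tnfaip3 rose by 1.78 ± 0.14 (1.39e-05), Icam1 by 2.21 ± 0.25 (0.00244), Nos2 by 3.51 ± 0.38 (0.0063) and C3 by 5.17 ± 0.25 (7.08e-08). There the quinone reductase Nqo1 rose by 1.68 ± 0.19 (0.000656) and Aurkb by 0.79 ± 0.12 (0.00204), while Sval1 fell by 2.22 ± 0.26 (0.00484) and the fucosyltransferase Fut2 fell by 1.04 ± 0.11 (0.00016). These were called with each library left out, and the calls of Slc7a11 and Fut2 were lost with cells at 1000 UMIs. Nos2 in the libraries labelled wildtype rose by 3.49 ± 0.37 (0.00629; 0.0722 without wildtype untreated replicate 2). Duox2 in those labelled knockout rose by 1.22 ± 0.22 (0.0122; 0.0694 without knockout TNF replicate 1 and 0.0567 without replicate 2). Muc2 was called in neither (-2.79 ± 0.66, 0.144, and -2.97, 0.0674). With the line as a block it was called in wildtype and knockout (3.02e-19 and 7.62e-24), as it was without knockout untreated replicate 1 (4.26e-06 and 5.86e-05) or 2 (5.93e-06 and 5.35e-07).

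In counts, TNF called 499 genes (256 up, 243 down) in the libraries labelled wildtype and 785 (422 up, 363 down) in those labelled knockout. The wildtype count was 282 (132 up, 150 down) without wildtype untreated replicate 1 and 216 (79 up, 137 down) without replicate 2. It was 161 (79 up, 82 down) without wildtype TNF replicate 1, 297 (176 up, 121 down) without replicate 2, and 299 (112 up, 187 down) in cells at 1000 UMIs or more. So the balance of up and down in that group depends on single libraries and on the cell filter. The wildtype count was 774 without knockout untreated replicate 1, 770 without replicate 2 and 1783 with the line as a block. The knockout count was 384 (239 up, 145 down) without knockout untreated replicate 1 and 1947 (900 up, 1047 down) without replicate 2. It was 323 (178 up, 145 down) without knockout TNF replicate 1, 279 (186 up, 93 down) without replicate 2, and 2611 (1187 up, 1424 down) with the line as a block. Both called 300 genes, each in the same direction (156 up and 144 down, against 7.3 and 6 for independent lists). Across genes the changes correlated at Pearson 0.677 and Spearman 0.566, where genes are not independent replicates. Proliferation genes were called up in the libraries labelled knockout (14 of 22, 20 adjusted over the list alone; median 0.58, camera adjusted p 2.86e-17; adjusted p = 0.296 with an estimated correlation). The share of proliferating-like cells rose there too, by 14.732 and 7.123 points in the 2 lines against 0.631 and 2.532 in those labelled wildtype. Goblet genes were called down by camera in the libraries labelled knockout (8 of 20, 16 adjusted over the list alone; median -1.67, 1.51e-19; fry 0.0431, and 0.279 with an estimated correlation). The same held in those labelled wildtype (9 of 20, 14 adjusted over the list alone; median -2.21, 4.81e-19), where fry gave 0.0765 and the estimated correlation 0.249. Camera also called the enteroendocrine list down in each group (1.04e-10 in those labelled knockout, 1.15e-06 in those labelled wildtype). Most of its members did not pass there (2 of 22, 5 adjusted over the list alone, and 1 of 22, also 1 adjusted over the list alone). Fry gave 0.156 and 0.372, and the estimated correlation 0.332 and 0.422, so a fall of these genes within one genotype is not established. Of the 2 untreated libraries labelled knockout, replicate 1 had 12.14% free RNA. In the libraries labelled wildtype proliferation genes were not called (0 of 22 by edgeR, and 0 adjusted over the list alone; median 0.07, camera adjusted p 0.151). Cholesterol synthesis was called down in those labelled knockout (4 of 18, 10 adjusted over the list alone; median -0.32, 1.05e-05; adjusted p = 0.332 with an estimated correlation). The interferon response was called up in those labelled wildtype (4 of 23, 15 adjusted over the list alone; median 0.70, 4.29e-12; adjusted p = 0.249 with an estimated correlation) against a median of 0.09 (0.193) in those labelled knockout.

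**Figure D3:**
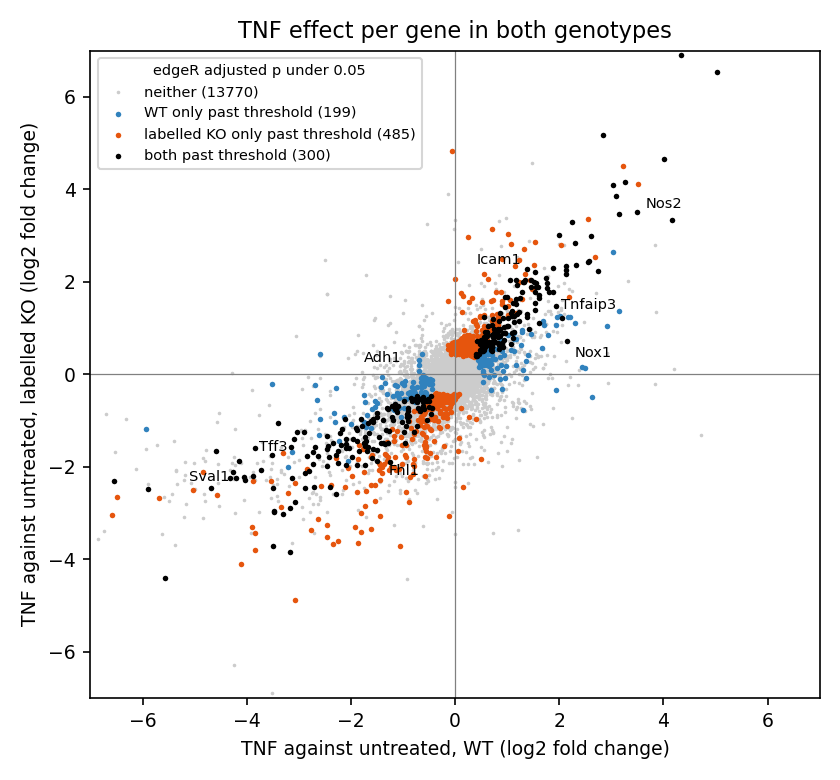
Log2 fold change with TNF per gene in the libraries labelled wildtype (x axis) and knockout (y axis), 2 TNF against 2 untreated libraries each, coloured by where edgeR called the gene. The 300 genes called in both lie on the same side of 0 in each, 199 were called only in wildtype, 485 only in knockout and 13770 in neither, and 11 genes lie outside the axes.

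Whether the TNF change differed by genotype was asked through the interaction. The smallest p-values belonged to C3, with a larger rise in the libraries labelled knockout (2.35 ± 0.33, edgeR adjusted p 0.129), and the retinol dehydrogenase Adh1 (ENSMUSG00000074207, chromosome 3; 1.18 ± 0.20, 0.238). Next were Slc7a11, which supplies cystine for glutathione (-1.21 ± 0.20, 0.238), Nox1 (-1.42 ± 0.26, 0.466), Ncf4 (1.07 ± 0.21, 0.466). The desaturase Scd1 (ENSMUSG00000037071, chromosome 19; -0.74 ± 0.15, 0.466) and the interferon gene Ifit1 (ENSMUSG00000034459, chromosome 19; -2.28 ± 0.46, 0.466) followed. None of these passed the threshold. With the line as a block they were called (C3 6.25e-14, Adh1 3.31e-06, Slc7a11 6.04e-11, Ncf4 0.000626, Scd1 0.00064, Ifit1 9.07e-07). So were Duox2 (-0.80 ± 0.19, 0.00306) and Tnfrsf11b (-0.59 ± 0.16, 0.0222), which the main fit did not call. The sizes hardly moved with the block (C3 2.39). Errors went from 0.33 to 0.28 for C3, from 0.26 to 0.17 for Nox1 and from 0.21 to 0.22 for Ncf4. The p-values fell much further than this, for a reason that was not tested, so they are not read as stronger evidence. edgeR called 0 of 14754 genes and 645 had an unadjusted p under 0.05. DESeq2 called 19, edgeR with no gene filter 74 and edgeR with the line as a block 312. Leaving out wildtype untreated replicate 2 gave 2 genes, C3 (2.66) and Nox1 (-1.79, both at 0.0303), and leaving out knockout untreated replicate 1 gave 3. Camera called 13 lists (7 without wildtype TNF replicate 1), and the calls of 3 held with each library left out. They were proliferation (0 of 22 called by edgeR, 15 up adjusted over the list alone; median 0.47, adjusted p 2.48e-21), cholesterol synthesis (0 of 18; median -0.30, 9.76e-10) and the interferon response (0 of 23; median -0.71, 1.19e-09), each at adjusted p = 0.563 with an estimated correlation.

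How the genotypes differed over both treatments was asked with 4 libraries labelled knockout against 4 labelled wildtype. These come from 2 lines per genotype, and the test counts the untreated and the TNF library of a line as separate. A difference between genotypes was not separated from one between lines. Secretory genes were higher in the libraries labelled knockout. Sval1 was higher by 4.86 ± 0.22 (edgeR adjusted p 6.99e-06) and the antimicrobial ribonuclease Ang4 (ENSMUSG00000060615, chromosome 14) by 4.32 ± 0.34 (0.000842). The protease inhibitor Spink1 (ENSMUSG00000024503, chromosome 18) was higher by 5.33 ± 0.44 (0.0015), Tff3 by 3.76 ± 0.32 (0.000826), Muc2 by 2.86 ± 0.43 (0.00949) and Isl1, a regulator of enteroendocrine cells, by 2.66 ± 0.24 (0.000417). Hoxd13 (ENSMUSG00000001819, chromosome 2, 74668310 to 74671599), a homeobox gene of the hindmost gut, was higher by 4.31 ± 0.47 (0.0041). Lower genes included malic enzyme Me1 (ENSMUSG00000032418, chromosome 9; -2.16 ± 0.10, 4.94e-08) and the glutathione transferases Gsta3 (ENSMUSG00000025934, chromosome 1; -1.48 ± 0.12, 8.61e-06) and Mgst1 (-1.24 ± 0.10, 3.24e-06), with the sulfiredoxin Srxn1 (-1.20 ± 0.08, 5.5e-07) and the pentose phosphate enzyme Pgd (-0.97 ± 0.08, 2.38e-06). Ddah1 (ENSMUSG00000028194, chromosome 3), which degrades inhibitors of nitric oxide synthases, was lower (-2.36 ± 0.10, 4.06e-08). So were the siderophore binder Lcn2 (-2.68 ± 0.27, 1.64e-05), the stem cell receptor Lgr5 (-1.71 ± 0.27, 0.00613), Noxa1 (-0.81 ± 0.09, 2.98e-05) and the carbonic anhydrase Car1 (-0.58 ± 0.11, 0.00246). All of these were called with each library left out. Cyba (0.26, 0.0735) was not called, though it was without wildtype untreated replicate 1 (0.038) or knockout untreated replicate 2 (0.0185), and Nos2 (-0.26, 0.478) was not. The Car1 call was lost with cells at 1000 UMIs or with a mitochondrial limit of 10%. In all 4855 genes were called, 2397 higher and 2458 lower.

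Camera called 10 lists between genotypes over both treatments, all lost with an estimated correlation. At adjusted p = 0.628 with an estimated correlation were goblet (17 of 20 up, 18 adjusted over the list alone; median 2.14, 1.5e-12), and enteroendocrine genes (19 of 22 up, also 19 adjusted over the list alone; 2.06e-09). Also at that value were antioxidant (2 up and 16 down of 22, the same adjusted over the list alone; 2.18e-06) and cholesterol synthesis (11 of 18 down, also 11 adjusted over the list alone; 1.52e-05), as well as deep crypt secretory (6 of 9 up; 0.000557) and regenerative genes (9 of 16 down; 0.000568). At adjusted p = 0.63 with an estimated correlation were proliferation (12 of 22 down, 15 adjusted over the list alone; 2.18e-06) and MHC class I (7 of 14 up, 8 adjusted over the list alone; 0.000799). Immediate early genes were up (8 of 20, 9 adjusted over the list alone; 0.00918, adjusted p = 0.63 with an estimated correlation; 0.0613 without knockout TNF replicate 1 and 0.0548 without knockout untreated replicate 2). Hypoxia genes were down (10 of 22, 1 up; 0.0162, adjusted p = 0.686 with an estimated correlation; 0.0598 without knockout untreated replicate 1 and 0.0613 without knockout TNF replicate 1).

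Genotype within each treatment was asked with 2 against 2 libraries. Untreated, Sval1 (3.94 ± 0.29, edgeR adjusted p 0.000292) and Ang4 (3.30 ± 0.45, 0.0127) were higher in the libraries labelled knockout. Me1 (-2.50 ± 0.15, 4.53e-06), Gsta3 (-2.09 ± 0.17, 4.65e-05), Nqo1 (-1.48 ± 0.19, 0.00085) and the mitotic kinase Plk1 (-0.79 ± 0.11, 0.000787) were lower. With TNF, Sval1 (5.78 ± 0.32, 5.27e-05), Ang4 (5.34 ± 0.50, 0.00331) and Tff3 (4.36 ± 0.47, 0.00397) were higher, and Me1 (-1.81 ± 0.14, 5.19e-06), Scd1 (-1.52 ± 0.10, 1.97e-06) and Slc7a11 (-1.35 ± 0.14, 6.12e-05) were lower. These were called with each library left out. Untreated, 2283 genes were called (1210 higher, 1073 lower; 982 without wildtype untreated replicate 1, 892 without replicate 2 and 1222 without knockout untreated replicate 1). With TNF 2421 were called (1311 higher, 1110 lower; 1066 without wildtype TNF replicate 1, 911 without replicate 2, 1096 without knockout TNF replicate 1 and 1032 without replicate 2, of which 707 higher and 325 lower). With cells at 1000 UMIs or more, 656 were higher and 325 lower untreated, and 958 higher and 535 lower with TNF. Both called 1381 genes, all in the same direction (810 higher, 571 lower; 107.5 and 80.7 for independent lists). Both comparisons use the same 4 lines, so a difference between lines recurs in both, and neither these expected counts nor a correlation of 0 is the value without a genotype effect. Across genes Pearson was 0.818 and Spearman 0.746. Goblet (13 of 20, 19 adjusted over the list alone; median 1.89, camera adjusted p 7.13e-15) and enteroendocrine genes (10 of 22, 18 adjusted over the list alone; median 3.17, 9.06e-12) were higher untreated, both at adjusted p = 0.56 with an estimated correlation. Proliferation genes were lower untreated (17 of 22, 22 adjusted over the list alone; median -0.51, camera adjusted p 6.8e-13; adjusted p = 0.56 with an estimated correlation). These 3 lists were called with each library left out, knockout untreated replicate 1 with much free RNA included. The share of proliferating-like cells was also lower untreated (28.4% against 39.1%). Proliferation genes were not called with TNF (median -0.05, 0.256). Cholesterol synthesis genes were lower with TNF (12 of 18, 16 adjusted over the list alone; median -0.43, 4e-08; adjusted p = 0.628 with an estimated correlation). Camera also called that list untreated, a call lost with the replicate number as a block.

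Whether the mixture of cells differed was asked with shares of cells per library, for which the smallest exact permutation p is 0.0556. Every library, untreated or TNF, was in medium with the Notch inhibitor DAPT, so the shares hold under that condition. For genotype this counts both libraries of a line as separate; with lines kept whole, 2 against 2, no p under 0.3333 is possible. Goblet-like cells, which make mucus, were 2.27 ± 0.226% of cells in wildtype untreated, 0.425 ± 0.026% in wildtype TNF, 7.05 ± 1.35% in knockout untreated and 3.06 ± 0.736% in knockout TNF libraries, as labelled (mean ± SD, n = 2). The mean difference was -2.918 percentage points for TNF and 3.704 for genotype (exact permutation p 0.0556 for both, adjusted 0.0927 and 0.1389). Clustered without the 6110 genes called inside classes, these were -4.19 and 10.877 (exact permutation p 0.0556 for both). They were -4.734 and 11.963 at resolution 0.4, -4.22 and 6.137 at 1.2, and -28.443 and 21.481 without integration. Muc2 was also higher in the libraries labelled knockout outside goblet-like and enteroendocrine-like cells (2.85 ± 0.42, edgeR adjusted p 0.00772, after free RNA was subtracted; free RNA was estimated at 0.185% to 2.47% of the Muc2 UMIs there). The cells outside include unnamed cluster 1, with Fcgbp and Tff3 among its leading genes, so this value does not tell changed expression from uncounted goblet cells. The goblet-like share was thus not separable from expression of its genes. Enteroendocrine-like cells, which make gut hormones, were 0.915 ± 0.329%, 0.058 ± 0.083%, 6.67 ± 4.09% and 1.87 ± 0.954% in the same order. The differences were -2.825 points for TNF and 3.782 for genotype (exact permutation p 0.0556 for both, adjusted 0.0927 and 0.1389), and -2.90 and 3.781 when clustered without those genes. Without knockout untreated replicate 1, the library with much free RNA, they were -1.378 and 2.336, and without replicate 2 of that group the TNF difference was -4.271. The enteroendocrine hormone gene Pyy also changed outside both classes, by -3.33 ± 0.52 with TNF (edgeR adjusted p 0.0108) and 5.35 ± 0.48 with genotype (0.000423) after free RNA was subtracted. Free RNA was estimated at 93.1% of the Pyy UMIs there in knockout untreated replicate 1 and 11.3% to 31.9% in 6 others, and wildtype TNF replicate 1 had 0 such UMIs. Chgb, the other enteroendocrine gene tested there, was called in neither comparison (-4.74 ± 1.39, 0.142, and 4.07 ± 1.41, 0.106). Whether this share is separable from expression of its genes was thus not settled. Enteroendocrine-like cells were 0 of 2950 cells in wildtype TNF replicate 1 (95% interval up to 0.125%). Proliferating-like cells were 39.1 ± 2.47%, 40.6 ± 3.82%, 28.4 ± 3.27% and 39.3 ± 2.11% (6.255 and -5.989 points, exact permutation p 0.1111 for both; 6.047 and -6.44 when clustered without those genes). Regenerative-like cells had means of 1.94% and 2.61% untreated and 3.23% and 4.14% with TNF (1.409 points for TNF, 0.0556, and 0.785 for genotype, 0.1111, exact permutation; 0.63 and 0.184 without those genes). Colonocyte-like cells differed by -0.912 (0.1667) and -0.902 (0.2222; -0.175 and -3.792 without those genes). In each of these 5 classes the TNF difference had the same sign in all 4 lines, with an exact sign-flip p of 0.125, the smallest possible. Without integration the genotype differences were -17.448 (proliferating-like), -9.588 (regenerative-like) and -5.838 (colonocyte-like). The shares come from libraries of unequal depth, knockout untreated replicate 1 having a median of 7165 UMIs per cell. The UMI threshold for a cell was also higher in each TNF library than in the untreated library of its line. Among cells at or above 8348.6 UMIs, the highest threshold, the TNF difference of goblet-like and enteroendocrine-like cells together was -4.21 points (pooled SD 2.14). In the main set it was -5.74.

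Clusters that reached no class by the naming thresholds held large parts of every library. In the order wildtype untreated, wildtype TNF, knockout untreated and knockout TNF, group means of the 7 unnamed clusters were 8.22, 4.51, 13.9 and 13.4% (cluster 0), 7.73, 5.94, 15.7 and 10.952% (cluster 1). They were 11.2, 12.4, 6.43 and 7.27% (cluster 3), 9.19, 7.79, 7.91 and 10.163% (cluster 5). The rest were 7.25, 9.5, 2.50 and 2.60% (cluster 8), 5.29, 8.03, 4.22 and 2.81% (cluster 9) and 2.50, 3.86, 0.91 and 1.76% (cluster 15). Leading genes included Guca2b, Guca2a and Atoh1 in cluster 0, Fcgbp and Tff3 in cluster 1 and Ccnb2, Cdkn3, Cenpa and Cdc20 in cluster 3. Cluster 8 had 5 colonocyte markers up and cluster 9 had 8 regenerative markers up. The shares of the named classes thus need not hold all cells with genes of their kind.

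**Figure D4:**
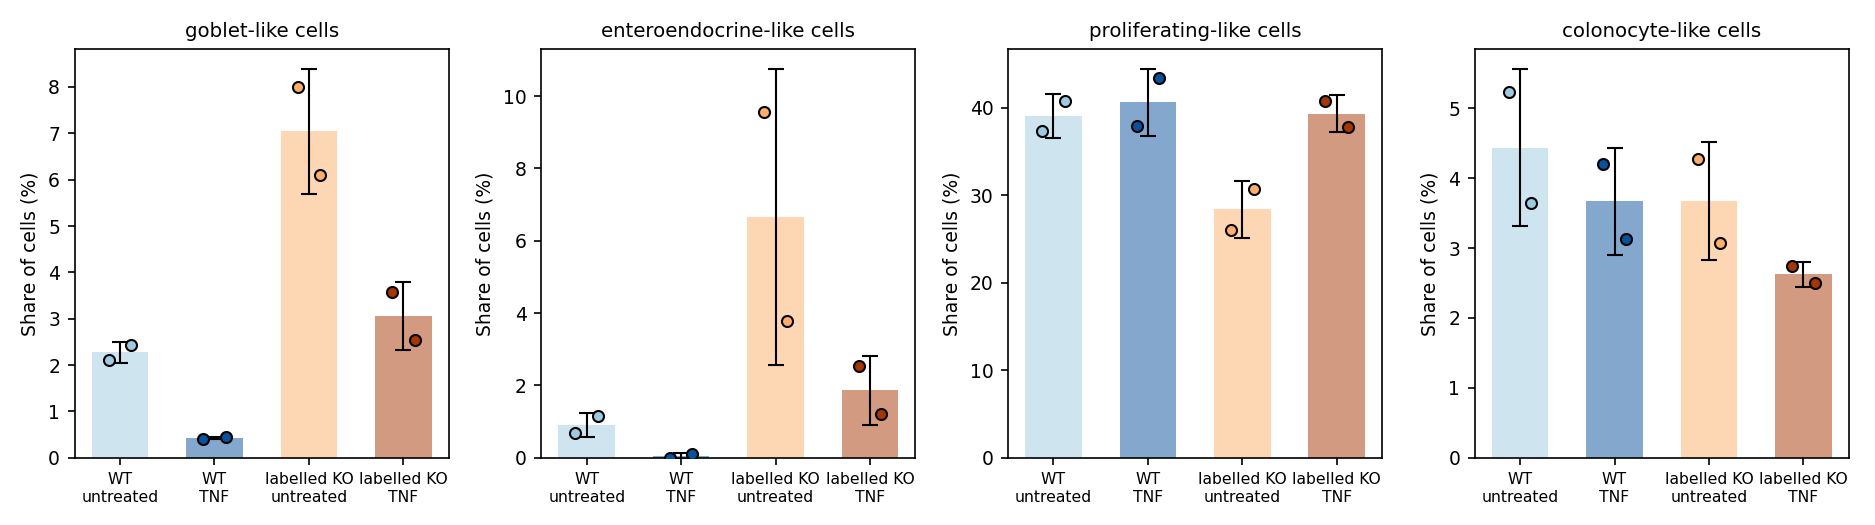
Share of cells (percent, y axis) in goblet-like, enteroendocrine-like, proliferating-like and colonocyte-like classes per group, bars the mean, error bars the SD and points the libraries (n = 2). Goblet-like cells stand at 7.05% in knockout untreated and 0.425% in wildtype TNF libraries, and the enteroendocrine-like points of knockout untreated lie far apart at 9.557 and 3.773%.

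M cells, the antigen-sampling cells of lymphoid follicles, formed no cluster. None, 0 of 16, was M-like, as were 0 of 11 and 0 of 20 at other resolutions and 0 of 16 without integration. Their surface receptor Gp2 had a UMI in 13 cells (1 in knockout untreated replicate 1, 6 in each knockout TNF library and 0 in the other 5). Their regulator Spib had one in 30 cells, and 0 of 34012 cells had both. The tuft cell channel Trpm5 was used as background, since no tuft-like cluster was named. It had a UMI in 0 to 0.122% of cells per library, against 0 to 0.122% for Gp2 and 0 to 0.183% for Spib. Median depths were 7165 to 15738 UMIs. A second tuft gene, Pou2f3, lay lower, at 0 to 0.02%. In the knockout TNF libraries Gp2 (0.111 and 0.122%) and Spib (0.166 and 0.183%) lay above Pou2f3, so the reading depends on the background gene. The M cell regulator Sox8, chosen after its values were seen, had one in 0 to 0.061% of cells in 7 libraries and in 0.295% (16 cells) in knockout TNF replicate 1. In free RNA Gp2, Spib, Trpm5 and Sox8 were at 0 CPM in each library. The free RNA of the knockout TNF libraries held 4510331 and 7182522 UMIs, while these genes reached at most 0.139 CPM in their cells. That depth is too low to show them reliably, so 0 CPM does not tell where the UMIs came from. A small share of M cells was thus not excluded. Osteoprotegerin Tnfrsf11b (ENSMUSG00000063727, chromosome 15) is the decoy receptor for the M cell inducing ligand. It changed by 1.42 ± 0.36 with TNF (edgeR adjusted p 0.0835). With the line as a block, a fit with fewer residual degrees of freedom, it was called (1.43, 2.51e-63) at nearly the same size. Tnfaip2, another M cell marker, did not pass over both genotypes (0.12 ± 0.47, 0.911). It rose with TNF in both lines labelled wildtype and fell in both labelled knockout. Its interaction was -1.65 (adjusted p 1) and was called with the line as a block (-1.62 ± 0.32, 0.00013). The RANK receptor Tnfrsf11a rose by 0.76 ± 0.08 (4.07e-05) and the peptidoglycan binder Pglyrp1, also on the M cell list, by 1.65 ± 0.11 (1.26e-06).

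Whether genes changed inside a class of cells was asked for the 3 named classes with at least 20 cells in every library, over both genotypes or treatments. Clusters 0, 1, 3, 5, 8 and 9, which stayed unnamed, also had enough cells. There edgeR called 169 to 1066 genes for TNF, 748 to 2384 for genotype and 0 to 3 for the interaction (265 to 575 at an unadjusted p under 0.05). In proliferating-like cells TNF raised the MHC class II chaperone Cd74 by 4.0 ± 0.16 (edgeR adjusted p 1.54e-10), Ncf4 by 3.28 ± 0.15 and Tnfaip3 by 1.90 ± 0.11. It lowered Sval1 (-3.39 ± 0.13, 1.54e-10) and the claudin Cldn2 (-1.65 ± 0.11, 7.08e-08). In colonocyte-like cells it raised Cd74 (edgeR adjusted p 2.19e-11) from 0 UMIs in each of the 4 untreated libraries to 97 and 95 in wildtype TNF and 83 and 36 in knockout TNF libraries, so the size of the rise is not determined. There it raised Pglyrp1 by 1.82 ± 0.13 and lowered the gasdermin Gsdmc4 (-3.29 ± 0.30, 3.42e-08, with 2 and 1 UMIs left in the wildtype TNF libraries). In regenerative-like cells it raised Nos2 by 2.21 ± 0.23 (1.99e-06) and Pglyrp1 by 1.00 ± 0.10 (9.12e-07) and lowered the cytochrome Cyp2c55 (-1.77 ± 0.18, 2.91e-06). Between genotypes Ddah1 was lower in the libraries labelled knockout in colonocyte-like (-2.38 ± 0.22), proliferating-like (-2.23 ± 0.10) and regenerative-like cells (-2.09 ± 0.16). Sval1 was higher in proliferating-like cells (5.96 ± 0.13, 6.69e-14, and 5.96 ± 0.13, 5.04e-14, after free RNA was subtracted, which was estimated at 0.542% to 10.4% of its UMIs there) and Adh1 in regenerative-like cells (4.44 ± 0.16, 8.02e-17).

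In counts, edgeR called 1061 genes for TNF in proliferating-like cells (547 without wildtype TNF replicate 1, 1666 without knockout untreated replicate 2, 2154 with the line as a block). For genotype it called 3933. In colonocyte-like cells it called 237 for TNF (154 without wildtype TNF replicate 1, 150 and 139 without knockout TNF replicates 1 and 2, 368 without knockout untreated replicate 2, 587 with the line as a block). For genotype it called 378 (199 without wildtype TNF replicate 2, 208 and 194 without knockout TNF replicates 1 and 2). In regenerative-like cells it called 59 for TNF (38 and 29 without wildtype untreated replicates 1 and 2, 17 and 37 without wildtype TNF replicates 1 and 2, 101 without knockout untreated replicate 2, 101 with the line as a block). For genotype it called 1453 (932 without wildtype untreated replicate 2, 868 without wildtype TNF replicate 2, 928 without knockout TNF replicate 2). The interaction called 2 genes in proliferating-like cells, Sval1 (2.75 ± 0.27, 0.000282) and Slc7a11 (-1.54 ± 0.19, 0.00377). The count became 1 without wildtype TNF replicate 1, 4 without wildtype untreated replicate 2, 6 and 18 without knockout untreated replicates 1 and 2, and 79 with the line as a block. It called 1 in colonocyte-like cells, the stress gene Ddit3 (1.77 ± 0.28, 0.0177; 1.74 ± 0.30, 0.0973 after free RNA was subtracted; 0 genes without wildtype untreated replicate 1, wildtype TNF replicate 2 or either knockout TNF library, 9 without knockout untreated replicate 2, 42 with the line as a block). It called 1 in regenerative-like cells, Cldn14 (adjusted p 0.0256, its size not determined with 14 and 7 UMIs in wildtype untreated and 0 and 3 in wildtype TNF libraries; 0 genes without either wildtype TNF library or wildtype untreated replicate 1, 9 without knockout untreated replicate 2 and 9 with the line as a block). Unadjusted, 439, 437 and 442 genes had an interaction p under 0.05 in these 3 classes in that order.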

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

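The tests of exchanged labels, of a transcript outside the deleted part, of a different mixture of cells, of the untreated knockout library, of cell calling, and the separate tests of enteroendocrine-like cells and of Muc2 were chosen only after the result was seen; the tests of free RNA for Nox1, combined clustering, colon segment, chromosome segment and other splits were written before. The combined clustering test was divided into its enteroendocrine and Muc2 parts after its value was known. The limit in the test of cell calling, the use of Pyy and the subtraction of free RNA outside the classes were set after earlier forms of these tests had been seen.

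Camera with the preset correlation called 13 gene lists for the TNF by genotype interaction, and fry called none of them. By camera they were proliferation (adjusted p 2.48e-21), cholesterol synthesis (9.76e-10), interferon response (1.19e-09), endoplasmic reticulum stress (6.53e-05), colonocyte (0.000375), mitochondrially encoded (0.00135), regenerative and fetal-type (0.00583), ribosomal protein (0.0104), NF-kB targets (0.0116), Paneth (0.025), enteroendocrine (0.0314), goblet (0.0419) and nuclear oxidative phosphorylation (0.0473). A difference of the TNF change between genotypes is thus not established for these lists. With an estimated correlation between genes the adjusted p was 0.563 for the first 3 and 0.629 for the other 10, and edgeR called 0 single genes (645 at an unadjusted p under 0.05; DESeq2 called 19). The first 3 lists were called with each library left out. Without knockout untreated replicate 1 the calls of endoplasmic reticulum stress (0.168) and colonocyte (0.189) were lost and the mitochondrially encoded genes turned the other way (0.0359). Without knockout untreated replicate 2 the calls of NF-kB targets (0.92), Paneth (0.942), enteroendocrine (0.942) and regenerative genes (0.063) were lost, and goblet (0.413) and nuclear oxidative phosphorylation (0.942) changed direction. Without wildtype untreated replicate 1 NF-kB targets (0.0867) and ribosomal protein genes (0.433) were lost and nuclear oxidative phosphorylation changed direction (0.718), and without wildtype untreated replicate 2 colonocyte (0.118), enteroendocrine (0.278), goblet (0.278), Paneth (0.0703) and regenerative genes (0.308) were lost. Without wildtype TNF replicate 1 enteroendocrine (0.14), goblet (0.413), nuclear oxidative phosphorylation (0.175), Paneth (0.206), regenerative (0.0783) and ribosomal protein genes (0.325) were lost, without wildtype TNF replicate 2 enteroendocrine (0.23), NF-kB targets (0.301) and Paneth (0.131), without knockout TNF replicate 1 enteroendocrine (0.105), goblet (0.412), NF-kB targets (0.15) and Paneth (0.121), and without knockout TNF replicate 2 nuclear oxidative phosphorylation (0.352) and ribosomal protein genes (0.583). With the line as a block, nuclear oxidative phosphorylation (0.133) and ribosomal protein genes (0.121) were lost.

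The barcodes below cell depth, which enter the comparisons only as the free RNA profile and, in the setting at 1000 UMIs, partly as cells, held a signal of their own: in knockout untreated replicate 1 free RNA was estimated at 12.14% of the UMIs in cells, against 1.42% at most in the other 7 libraries.

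The first pattern weighed is that Nox1 was higher in the 4 libraries labelled knockout than in the 4 labelled wildtype. The tables argue against free RNA, since the log2 fold change was 2.45 ± 0.15 (edgeR adjusted p 4.4e-06) after free RNA was subtracted, and against a different mixture of cells as the whole cause, since it was 2.23 ± 0.12 (1.05e-08) inside the proliferating-like class alone. Exchanged genotype labels stay open. All 4 of 4 libraries labelled knockout lay above every library labelled wildtype, which a full exchange would also give. No other value in the labels tells the genotypes apart. An exchange alone would not account for all Nox1 counts, since the libraries labelled wildtype also held 201 to 2038 Nox1 UMIs each. After an exchange these would be knockout UMIs and would still need a source, such as 3' ends outside the deleted part. A transcript counted outside the deleted part, such as 3' ends from an allele that still makes RNA, also stays open, since the 4 libraries held 22563 Nox1 UMIs and the labels do not name the deleted part. These 2 explanations cannot be told apart because 3' tags do not show which part of the gene was present, and a true rise of a disabled transcript in knockout cells was not tested.

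The second pattern is the higher share of goblet-like and enteroendocrine-like cells in the libraries labelled knockout, 7.49 percentage points for both classes together. The tables argue against the untreated knockout library with much free RNA as the whole cause (5.56 points without it, against a pooled SD of 1.03 in the other groups) and against cell calling at different depths as the whole cause (6.59 points, pooled SD of the 4 groups 2.14, among cells at or above 8348.6 UMIs, the highest of the 8 library thresholds). For the goblet-like cells, clusters formed by genes that respond to genotype or TNF are consistent with Muc2 being higher outside both classes by 2.85 ± 0.42 log2 units (edgeR adjusted p 0.00772) after free RNA was subtracted, which was estimated at 2.47% of those UMIs at most, so that part of the share may be a change of expression in other cells or goblet cells in unnamed clusters. For the enteroendocrine-like cells this stays open, because the share still differed by 3.78 points when clustered without those genes but Pyy was also higher outside both classes, by 5.35 ± 0.48 (0.000423) after free RNA was subtracted, which was 93.1% of those UMIs in knockout untreated replicate 1, and for both classes together it stays open because clustering without those genes gave 14.66 points but the goblet-like class grew from 1107 to 5890 cells, with 908 in both. A biological difference between the genotypes or between the lines in secretory cell numbers stays open as a hypothesis, and a difference in the age of the animals was not tested.

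The third pattern is the number of genes that differ between genotypes and with TNF, read against other ways to split the 8 libraries. For genotype, 1 of 35 splits of the libraries taken as separate, the real one, called as many genes (3123, the highest other 126). Those splits treat the 2 libraries of a line as exchangeable, which they are not. With both libraries of each line kept together there are 3 splits, too few for a share under 0.05 (3123 for the real one, 3 for the highest other). A chance difference between lines was thus not excluded. For TNF, fitted without a term for genotype, 2 of 35 splits called as many as the real 126, so this count alone does not exclude chance. The other is the genotype split with 3123, a structure of the samples. TNF tested in each genotype, on separate libraries, called 300 genes in both, all in the same direction (156 up and 144 down, against 7.3 and 6 for independent lists), which speaks against chance. Among the 8 splits that part all 4 pairs of the same line the real one gave 126 and the other 7 gave 0. These 8 are too few for a share under 0.05. The rule written before for a difference in colon segment was met: the 7 posterior Hox genes other than Hoxd13 had a median log2 fold change of 0.17 with 5 up. The median was -0.01 for 17 other Hox genes. Colon segment was still not decided, because the 3 posterior genes called up were Hoxd10, Hoxd11 and Hoxd12, the first at 0 UMIs in each library labelled wildtype. Hoxd9, outside the posterior set but next to them, was called up at 3.81. The 5 Hoxd genes tested, Hoxd9 to Hoxd13, were called and the other 4 posterior Hox genes were not. Hoxd9, Hoxd10 and Hoxd12 reached at most 0.494, 0.919 and 0.287 CPM in a library. A chromosome segment around Nox1 could not be decided either, at a Fisher's exact p of 0.277 (28 of 77 genes called within 20 Mb, 36.4%, against 101 of 338 on the rest of chromosome X, 29.9%). A difference between lines and a difference of genotype cannot be told apart, because each genotype is made up of 2 named lines of its own.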

How the results depend on the processing

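The settings without goblet-like and enteroendocrine-like cells and with free RNA subtracted inside classes, and printing blocked values beside the results, were chosen only after the result was seen; genes shown as list members were added to the alternatives at the end. A value that changed sign while past the threshold in neither fit was counted as kept (67 of 10803 values for 519 gene results), and 3 class shares changed sign. For genes named, the settings fixed beforehand, other than leaving out a library, kept direction and call in 5353 values, with 82 gaining and 178 losing a call, and leaving out 1 library kept 3650, with 18 gaining and 484 losing one. Losses were most frequent with cells at 1000 UMIs (89), without knockout TNF replicate 2 (80) and without wildtype untreated replicate 2 (74). For gene lists, leaving out 1 library kept 685 and lost 78, and the settings fixed beforehand kept 125 and lost 163. The settings with free RNA subtracted and without goblet-like and enteroendocrine-like cells, counted apart, kept 1007 values for genes named, with 3 gaining and 28 losing a call. The correlations across genes were counted as moved when they shifted by at least the standard deviation of the leave-one-out values. Leaving out 1 library moved all 16, the settings fixed beforehand moved 4 and kept 18, and the added ones moved 2 and kept 2. Within classes only the 3 classes named and 3 contrasts were tried. Unless stated, the cause was not tested.

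With 10 CPM in 2 libraries, which tests fewer genes, counts in the order TNF in wildtype, TNF in knockout, genotype untreated, genotype with TNF, TNF averaged and genotype averaged were 256, 404, 1350, 1278, 870 and 2742. With cells at 1000 UMIs or more (90489 cells, 53833 of them from knockout untreated replicate 1) they were 299, 347, 981, 1493, 1019 and 3222. With no gene filter TNF in wildtype gave 1081, TNF in knockout 1665, TNF averaged 2487 and the interaction 74; within classes it gave 397 and 17 (colonocyte-like, TNF and interaction), 24 (proliferating-like interaction) and 147 and 14 (regenerative-like). DESeq2 gave 19 for the interaction, and within classes 147 and 204 (colonocyte-like, TNF and genotype), 9 (proliferating-like interaction) and 35, 716 and 0 (regenerative-like TNF, genotype, interaction). Without goblet-like and enteroendocrine-like cells the interaction gave 1. With free RNA subtracted inside classes the colonocyte-like interaction gave 0 (445 at an unadjusted p under 0.05), as Ddit3 had an adjusted p of 0.0973.

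With the replicate block, the line within genotype for TNF and the interaction, counts were 1783 (TNF in wildtype), 2611 (TNF in knockout), 3577 (TNF averaged) and 312 (interaction); within classes 587 and 42 (colonocyte-like), 2154 and 79 (proliferating-like) and 101 and 9 (regenerative-like) for TNF and interaction. For genotype the block is only a shared replicate number. There the calls of Muc2 (0.062) untreated and of Pyy averaged (0.0868) were lost, and cholesterol synthesis (0.0611), nuclear oxidative phosphorylation (0.0714) and Paneth (0.0611) untreated. In TNF in knockout the block lost Ccl20 (0.097) and nuclear oxidative phosphorylation (0.141). Paired shares had an exact sign-flip p of 0.125 at best, the smallest possible.

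Camera with an estimated correlation, which rests on 4 residual degrees of freedom, called 0 lists in each of the 7 contrasts. It thus does not tell which lists changed and which did not. Fry, which does not compare a list with other genes, called 5 (TNF in wildtype), 8 (TNF in knockout), 1 (genotype untreated), 4 (genotype with TNF), 0 (interaction), 14 (TNF averaged) and 12 (genotype averaged). Tests of shares by edgeR on cell counts passed where 36 relabelings could not: log2 ratios of -2.77 and 3.76 (enteroendocrine-like, TNF and genotype), -1.80 and 2.23 (goblet-like) and 0.71 (regenerative-like, TNF).

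Leaving out 1 library, the lone library of its group being assumed to vary like the other groups, gave counts of 161 to 774 (TNF in wildtype), 279 to 1947 (TNF in knockout), 892 to 2946 (genotype untreated), 911 to 3196 (genotype with TNF), 0 to 3 (interaction), 877 to 2693 (TNF averaged) and 3316 to 5312 (genotype averaged). Lists called were 14 to 18, 16 to 19, 10 to 15, 9 to 11, 7 to 14, 15 to 21 and 8 to 13 in that order. Within classes, TNF, genotype and interaction gave 139 to 368, 194 to 365 and 0 to 9 (colonocyte-like), 547 to 1666, 2713 to 4154 and 1 to 18 (proliferating-like) and 17 to 101, 868 to 1636 and 0 to 9 (regenerative-like). Shares for TNF and genotype gave -1.311 to -0.513 and -1.301 to -0.503 points (colonocyte-like), -4.271 to -1.378 and 2.336 to 5.228 (enteroendocrine-like), -3.394 to -2.442 and 3.228 to 4.18 (goblet-like), 4.905 to 7.604 and -7.339 to -4.64 (proliferating-like) and 1.141 to 1.677 and 0.516 to 1.053 (regenerative-like). Lists that reversed were mitochondrially encoded genes without knockout untreated replicate 1 (adjusted p 0.0174 for TNF in knockout, 0.0359 for the interaction), nuclear oxidative phosphorylation for the interaction without wildtype untreated replicate 1 (0.718) or knockout untreated replicate 2 (0.942), and goblet for the interaction without knockout untreated replicate 2 (0.413). Leaving out 1 library, the adjusted p ranged from 9.04e-10 to 0.0826 (mitochondrially encoded, TNF in knockout), 2.7e-15 to 0.0359 (the same, interaction), 3.53e-07 to 0.942 (nuclear oxidative phosphorylation, interaction) and 3.77e-09 to 0.413 (goblet, interaction).

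The goblet-like share moved with the clustering: for genotype 3.704 points as reported, 11.963 at resolution 0.4, 6.137 at 1.2 and 21.481 without integration. Tests of an M-like share gave no value, as no M-like cluster was found. In simulated counts with 2 libraries in each of 4 groups, 50.7% of 2-fold and 74.2% of 4-fold single-gene interactions were recovered. Other depths were not simulated.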
